A study of Rattus norvegicus with 2 samples.

How the data were processed

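RNA of newborn rat epidermal keratinocytes was measured on GeneChip arrays, after whole-transcript labelling of total RNA with biotin, per the labels' protocols. The series holds 2 arrays, 1 of cells kept for 5 days with 5 µM all-trans retinoic acid (RA) and 1 of cells kept for 5 days without it. The title of the second array carries no treatment mark. It was taken as the vehicle control because the series' design text names only RA and vehicle. Groups were taken from the sample titles.

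The deposited table gives 1 log2 signal per probe set and array, for 70580 probe sets. The authors' processing used RMA (robust multi-array average) and the Transcriptome Analysis Console, per the submitters' processing notes, which give no version and no order of steps. The log base was read from the values, since the table has no header that states it. RMA means background correction, normalization between arrays and summary of probes. The deposited columns do not share 1 distribution, which alone does not go against normalization of the probes before their summary. Both columns end at the same highest value, 19.93. On the array without RA 963 values lay above 16, which is the log2 ceiling of a 16-bit scanner image, and on the RA array 670 did. The values were therefore stretched beyond the scanner's scale in a step that the sources used here do not give, and a difference of 1 log2 unit (called 2-fold below) is 2-fold on the deposited scale only. A genome build is not given in the sources used here, so no coordinates are printed. Depth does not apply to arrays. Their number, 1 per group, limits the precision, and no detection calls were used.

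Genes were named from the platform annotation of the probe sets. Of the probe sets, 23446 had 1 gene symbol, 505 had several and 46629 had none. Those with several or none were left out of all gene results. Symbols were updated through the Entrez gene ID against the RefSeq gene table of assembly GRCr8, where 22077 of the 1-symbol probe sets matched and 1 symbol changed. A gene with several probe sets was represented by the one with the highest mean of the 2 arrays. Of 628 genes with several probe sets above the floor, 41 had probe sets that differed by over 1 log2 unit in their difference, and 0 had probe sets at least 1 unit apart from 0 in opposite directions. Genes absent from the 1-symbol probe sets, such as Krt5 and Krt6a, were not analysed here.

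The following was computed from the deposited log2 values, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6. The difference of each gene is the RA array minus the array without RA. With 1 array per group no test, standard error or p-value can be had, and none is given. A gene was counted as above the floor where the higher of its 2 values reached 3.81, the median of all values on both arrays, which left 14274 of 22093 genes. For 30 gene lists fixed before the data were examined, the median difference of the members above the floor was set against the medians of 10000 random lists of the same size, drawn from genes above the floor and matched on mean signal in 20 bins. A list outside the central 95% of these medians is called apart. The percentile describes these 2 arrays and says nothing about other cultures. The named genes were fixed by a rule before the data were examined. They are the 15 genes with the largest positive and the 15 with the largest negative difference among genes above the floor, leaving out predicted genes, small and ribosomal RNAs and olfactory and vomeronasal receptors by the start of their symbols, then the retinoid list, then the 4 members with the largest difference in each other list.

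The counting of genes was tested on simulated data made from the means of the 14274 genes. For this comparison, 84% of 50 genes shifted by 1.5 log2 units and 90% of 50 shifted by -1.5 units were counted at 2-fold, as were 100% of those shifted by 3 and by -3 units. Of the 14074 genes left unshifted, 6.29% were counted too, at a spread taken from the real differences, which holds real changes as well as noise. The lists were checked on the real differences instead. Of 400 random lists of 20 genes, 6% were called apart. These lists came from the same genes as the lists they were set against, which fixes this share nearly in advance. All of 100 lists shifted by 0.5 log2 units were called apart. Neither check covers lists whose members vary together.

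The alternatives tried were centring each array on its median, a lowess curve over all probe sets (span 0.2), a further quantile normalization, the mean of a gene's probe sets, raising values to the floor, no floor, a floor at the 75th percentile (5.45), thresholds of 1.5-fold and 4-fold, the mean in place of the median of a list, and each list without its most changed member. A lowess curve over probe sets with 1 gene, the removal of genes at the highest value and the median of absolute differences were added after the data were seen.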

Results

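Gene expression was measured in newborn rat epidermal keratinocytes (NRK cells), the cells of the outer skin layer kept in culture in medium with 10% serum. The cells of one array received 5 µM all-trans retinoic acid, the vitamin A metabolite that binds the nuclear retinoic acid receptors, and those of the other did not. The labels do not say whether an array holds RNA of a single culture or of several pooled. Medium was renewed every 24 h, and RNA was taken at day 5. Each group holds 1 array, so that no value below has a replicate or an error, and no difference could be set against the spread between cultures. All levels are log2 signals as deposited, and all differences are the RA array minus the array without RA, in log2 units. Control probe sets gave different ranges. The 92 spike sequences had a median of 3.28 without RA and 3.29 with RA, and the central 95% of their differences ran from -0.43 to 0.25. Most of these sequences lay at background, so this range does not cover bright genes. The 399 probe sets named as rat positive controls were brighter, with medians of 10.24 without RA and 10.28 with RA. The central 95% of their differences ran from -1.72 to 2.14, with 50 at least 2-fold higher and 61 at least 2-fold lower. The 8 labelling and hybridization controls had a median difference of -0.27. For the 1153 probe sets named as rat negative controls, whose signals reached 18.21, the central 95% of differences ran from -2.17 to 2.01, with 137 at least 2-fold higher and 181 at least 2-fold lower. Signals near or under the floor of 3.81 may be background, and a difference that reaches them, here and below, may then be smaller than the true one.

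The comparison asks which genes differ after 5 days of RA. Of 14274 genes above the floor, 1125 (7.88%) were at least 2-fold higher with RA and 804 (5.63%) at least 2-fold lower. Probe sets with no gene name had the opposite balance, 664 higher and 1343 lower of 21322 above the floor, and over all 70580 probe sets, with no floor, 2032 were higher and 2442 lower. Of the 1153 rat negative controls, also with no floor, 137 were higher and 181 lower, a larger share than of the genes. The medians of these controls, 4.57 without RA and 4.47 with RA, lay above the floor, so that the floor does not mark detection. For the genes, at 4-fold the counts were 435 and 285, and at 5 log2 units 60 and 62. Higher genes made up 58.3% of those changed at least 2-fold, and 69.3% when a lowess curve over all probe sets was removed first, which moved the median difference of genes above the floor from -0.026 to 0.075. With a lowess curve over probe sets with 1 gene only, added after the data were seen, the share was 61.0% and the median 0.013. Across these genes the 2 arrays correlated with a Pearson r of 0.923 and a Spearman rho of 0.932. These correlations are across genes, which are not independent replicates. There were 18 genes at the highest value on both arrays, for which no difference can be given.

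**Figure D1:**
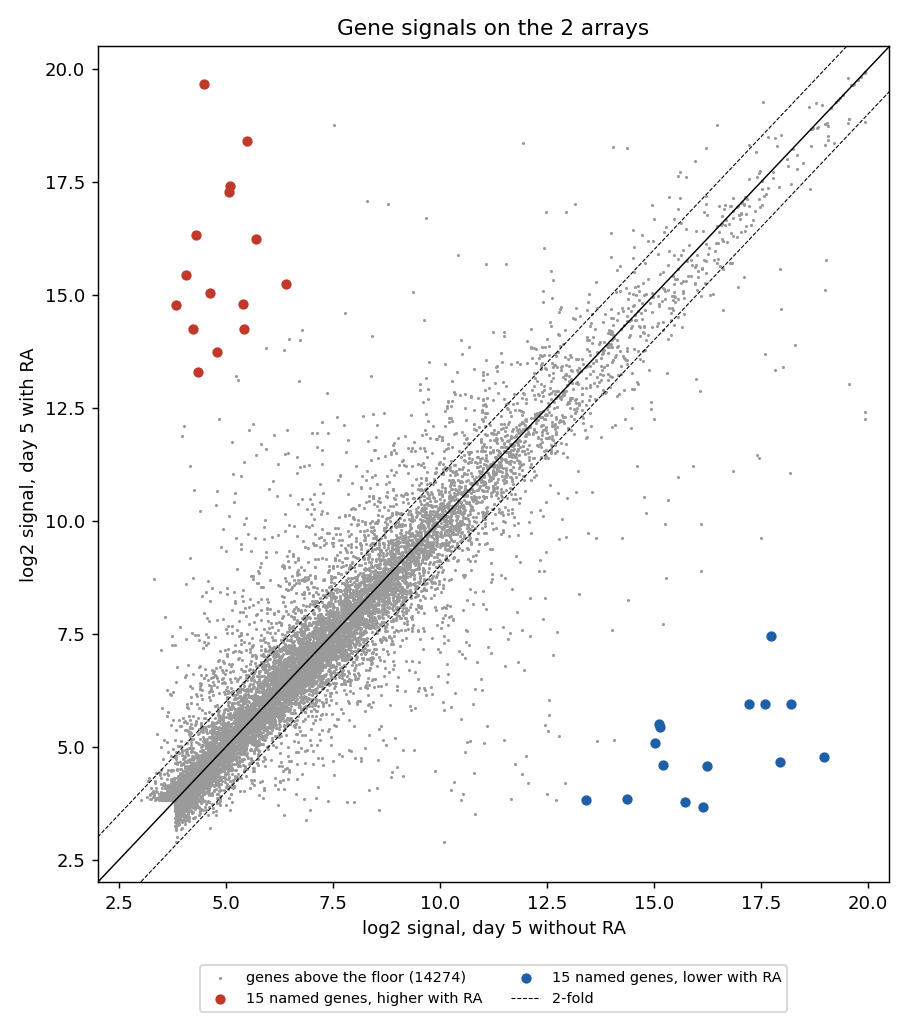
Log2 signal of each gene above the floor without RA (horizontal axis) and with RA (vertical axis), 1 array each. The solid line marks equal values and the dashed lines 2-fold, and the 15 named genes in each direction lie between 8.83 and 15.2 units above or 9.61 and 14.2 units below the solid line.

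Most of the genes furthest lower with RA were genes of the differentiated epidermis. Krt1 and Krt10, the keratin pair of the suprabasal layers, went from 18.98 to 4.78 and from 17.59 to 5.94. Krtdap, a keratinocyte differentiation-associated protein, was 13.27 units lower, and Calml5, a calmodulin-like skin protein, went from 16.14 to 3.67. Cnfn (cornifelin, of the cornified envelope) was lower by 12.25 units, Dsg1 (a desmosomal cadherin of the upper epidermis) by 11.66 and Cdsn (corneodesmosin, an adhesion protein of the cornified layer) by 11.25. Dmkn and Sbsn, secreted proteins of the suprabasal epidermis, were lower by 10.61 and 9.62, and the late cornified envelope genes Lce3b and Lce3fl1 by 10.29 and 9.71. Serpinb12 and Serpinb3a, clade B serine protease inhibitors, were lower by 10.51 and 9.95. C18h5orf46 and Tmem45a2 completed the 15, lower by 11.93 and 9.61. Of these 15 genes, 10 belong to the spinous or cornified lists.

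The genes furthest higher with RA came from several groups. Mmp7 (matrilysin, a protease of glandular epithelia) had the largest difference, from 4.48 to 19.68. Plet1, a surface protein, went from 5.48 to 18.41, and Cyp2s1, a cytochrome P450, from 5.09 to 17.40. Krt4, a keratin of stratified mucosal epithelia such as the oesophagus, went from 5.06 to 17.28. Stra6, the cell surface receptor for retinol-binding protein, was higher by 12.02 units, and Clca4l, of the calcium-activated chloride channel regulator family, by 11.38. Islr was higher by 10.93, Prss22 (a trypsin-like serine protease) by 10.52, Tnfsf9 (the 4-1BB ligand) by 10.41 and the complement component C3 by 10.01. Cgnl1, a junctional protein, was higher by 9.40, the membrane mucin gene Muc4 by 8.94, the cytokine gene Il1a by 8.94, the imprinted gene Peg10 by 8.84 and Tmem176a by 8.83. Of these 15 genes, 5 belong to a gene list. The lower values of these 30 genes ran from 3.67 to 7.45.

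**Figure D2:**
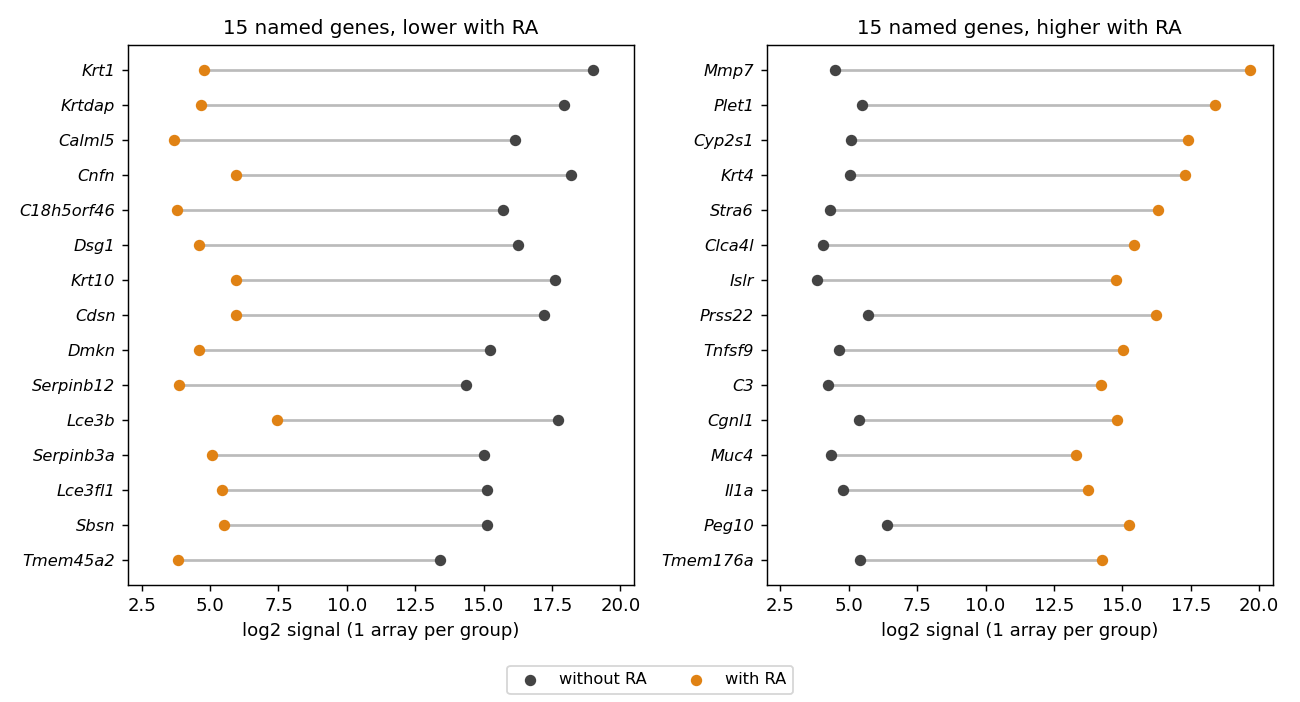
Log2 signal without RA (grey) and with RA (orange) of the 15 named genes lower and the 15 higher with RA, in order of their difference, 1 array per group. Krt1 went from 18.98 to 4.78 and Mmp7 from 4.48 to 19.68.

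Genes of retinoid handling and known RA responses differed in both directions. Of 28 members above the floor, 6 were at least 2-fold higher with RA and 6 at least 2-fold lower. The higher ones were Stra6, Tgm2 (tissue transglutaminase, 4.84 to 12.25), Dhrs3 (a retinal reductase, 6.70 to 13.09), Gprc5a (an RA-inducible receptor, 7.59 to 12.29), Rai14 (8.08 to 9.92) and Cyp26b1 (an RA-degrading enzyme, 4.17 to 5.96). The lower ones were Sdr16c5 (a retinol dehydrogenase, 12.55 to 5.71), Fabp5 (epidermal fatty acid binding protein, 18.99 to 15.10), Rxra (10.78 to 8.16), Rdh11 (lower by 1.86), Crabp2 (6.72 to 5.35) and Rara (7.07 to 5.92). Rarb, the RA receptor beta, was at 3.92 without RA and 3.85 with RA, close to the floor, and Rarg at 6.98 and 7.29. The list's median difference was -0.12, at the 12.4th percentile of matched random lists, whereas its mean was 0.59, at the 99th percentile of random means. The list as a whole therefore gave no single direction.

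Lists of keratinocyte differentiation were lower as groups. Of 21 spinous genes above the floor, 18 were at least 2-fold lower and 1 higher, and the median difference of -3.21 lay below all 10000 matched random lists. The 4 largest differences were those of Krt1, Krtdap, Calml5 and Dsg1. Of 32 cornified envelope genes, 23 were lower and 4 higher, with a median of -2.90, also below all random lists. Beside Cnfn, Cdsn and Lce3b, the protease gene Klk7 went from 12.93 to 4.19. Of 20 genes of the epidermal lipid barrier, 12 were lower and 2 higher, with a median of -1.47. They included Abca12, the lipid transporter of lamellar granules, from 12.46 to 5.49, Alox12b, an epidermal lipoxygenase, from 10.32 to 4.22, and the fatty acid elongases Elovl4 and Elovl7, lower by 6.52 and 3.73. The Sprr, Lce, serpin and keratin genes have close relatives, and their probe sets may share signal.

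Basal keratinocyte genes differed in both directions. Of 17 genes, 6 were at least 2-fold lower and 4 higher. Krt14, the main type I keratin of the basal layer, was at the highest value without RA and at 12.25 with RA, so that it was lower by at least 7.68 units. Col17a1, a hemidesmosomal collagen, went from 11.96 to 6.71. Itga3, an integrin subunit, went from 10.41 to 15.88 and Syt8 from 5.75 to 8.89. The list's median of -0.39 was at the 3.44th percentile, inside the central 95%, and fell outside it after a lowess curve over all probe sets (0.195th percentile) or a further quantile normalization (0.78th percentile). The median of the absolute differences, 1.70, was at the 99.99th percentile.

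Keratins of simple and mucosal epithelia also went both ways, 3 of 8 higher and 3 lower. Krt7, a keratin of simple epithelia, went from 11.94 to 18.37, Krt4 had the values given above, and Krt19 was at 8.15 and 10.72. Krt23 went from 10.64 to 5.11. The list's median was -0.080 and its mean 1.54, at the 98.9th percentile of random means. Among 18 mucous and secretory genes above the floor, 8 were at least 2-fold higher and 3 lower, and the median of 0.29 was at the 99.8th percentile. The mucin genes Muc4 and Muc13 (6.94 to 11.24) were higher, and Slpi, a secreted protease inhibitor, and Muc15 were lower by 3.63 and 3.39. The other 18 measured members were under the floor on both arrays, and with them in the list the median was at the 93.2nd percentile.

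Of 15 tight and gap junction genes, 5 were at least 2-fold higher and 2 lower, with a median of 0.52 at the 99.8th percentile. The claudin genes Cldn3 and Cldn4 went from 4.89 to 9.42 and from 14.05 to 18.27, Tjp3 from 5.74 to 8.20, and Cldn1, the main claudin of epidermis, from 17.94 to 15.57. Of 16 desmosome and adherens junction genes, 8 were lower and 2 higher, with a median of -0.78 at the 0.03rd percentile. The 4 largest differences were in desmosomal genes. Dsg3 was lower by 6.18 units, desmoplakin (Dsp) by 4.60, Dsc3 by 4.50 and plakophilin 1 (Pkp1) by 4.40. The 2 higher genes, named after their values were seen, were the desmosomal Pkp2, by 3.71, and Ctnnd1, by 1.10. Without Dsg3 the median was -0.46, at the 3.37th percentile and inside the central 95%.

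Lists of immune and wound-related genes had medians of opposite signs. Of 13 wound keratins and alarmins, 8 were at least 2-fold lower and 3 higher, with a median of -1.32, below all 10000 random lists. Krt16 and Krt17, keratins of wounded epidermis, were lower by 8.93 and 6.53. The 3 higher genes included Lcn2, by 1.90, named after its value was seen. The interleukin-36 genes Il36g and Il36rn went from 12.71 and 10.81 to 3.83, close to the floor, and 3.51, under it. Of 26 interferon response genes, 15 were at least 2-fold higher and 0 lower, with a median of 1.53, above all random lists. Gbp2 went from 5.14 to 11.75, Mx1 from 4.79 to 10.65 and Oasl from 3.32, under the floor, to 8.72, and the transcription factor gene Irf1 was higher by 4.71. Of 20 cytokine and chemokine genes, 10 were higher and 1 lower, with a median of 0.98, above all random lists. Beside Il1a, Csf3 went from 4.54 to 8.43 and Il33 from 4.54 to 7.50, while Ccl20 went from 10.95 to 6.50. Among 15 matrix proteases and inhibitors, 2 were higher and 4 lower, and the median of -0.22 (5.84th percentile) differed in sign from the mean of 0.58. It came outside the central 95% after quantile normalization (2.48th percentile) or with the floor at the 75th percentile (1.18th). Mmp7 and the collagenase gene Mmp13 (8.20 to 12.31) were higher, and Serpinb2 and Mmp28 lower by 6.08 and 1.29.

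Cell cycle genes were higher as a group. Of 42 genes, 15 were at least 2-fold higher and 0 lower, and the median of 0.66 lay above all 10000 random lists. Cyclin D1 (Ccnd1) went from 7.24 to 11.57, the replication gene Mcm5 from 7.84 to 11.79, the mitotic kinase gene Aurkb from 5.63 to 8.78 and thymidine kinase 1 (Tk1) from 7.85 to 10.60. Of 19 endoplasmic reticulum stress genes, 6 were higher and 0 lower, with a median of 0.75 at the 99.98th percentile. Creb3l2 and Asns were higher by 2.31 and 2.22, and the chaperones Hspa5 and Hsp90b1 by 1.78 and 1.47. Of 22 cholesterol and fatty acid synthesis genes, 7 were higher and 0 lower, with a median of 0.52 at the 99.87th percentile, and Sc5d, Insig1, Elovl6 and Fasn were higher by 2.10, 1.93, 1.84 and 1.59. By the mean of 0.64 this list was at the 96.8th percentile, inside the central 95%.

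In the TGF-beta and BMP list, 7 of 22 genes were at least 2-fold higher and 2 lower, with a median of 0.30 at the 99.86th percentile. Id2, an inhibitor of differentiation, went from 8.29 to 17.07 and Smad3 from 6.20 to 8.01, while Tgfbi and follistatin (Fst) were lower by 5.32 and 1.77. Growth factor genes of keratinocytes had a median of 0.29 at the 96.8th percentile, inside the central 95%, with 5 of 14 higher and 2 lower. It came outside after a further quantile normalization (98.4th percentile), with the mean of a gene's probe sets (98.8th) or with the floor at the 75th percentile (97.7th). Epgn, Pdgfa, Nrg1 and Vegfa were higher by 3.23, 2.35, 2.35 and 2.28.

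The other lists within the tissue lay inside the central 95%. Among 15 Hox and homeobox genes above the floor, 0 were at least 2-fold higher and 1 was lower, Dlx3 (10.02 to 7.62), with a median of 0.0051, and Hoxa9, Hoxc13 and Hoxa7 differed by -0.93, -0.76 and -0.45. Wnt genes had a median of 0.098 with 1 of 14 higher and 3 lower, among them Lgr4 (12.10 to 8.30), Fzd6 (11.98 to 10.67) and Fzd1 (5.01 to 3.71), and Wnt10a was higher by 1.38. Oxidative stress and xenobiotic genes had a median of -0.086, which was 0.090 after centring each array on its median, with 4 of 20 higher and 3 lower. Txnrd1, Cat and Akr1b8 were higher by 3.51, 1.91 and 1.85, and Slc7a11 went from 7.46 to 5.03. Ribosomal protein genes had a median of -0.12 (27.7th percentile), which was 0.31 after lowess over all probe sets. Of these 27 genes 1 differed by 2-fold, Rps19, lower by 1.07, and Rpl3, Rps18 and Rps3 differed by -0.82, -0.68 and -0.51. Of 14 reference genes, 4 were at least 2-fold higher, B2m, Tfrc, Pgk1 and Tubb5, by 2.57, 1.94, 1.87 and 1.23, and 0 were lower. The median of this list was 0.17, 0.89 after lowess over all probe sets (95.9th percentile) and 0 without B2m.

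Markers of other cell types that such a culture could hold lay on both sides of the floor. Of 91 markers in 7 lists, 44 were above it, 3 were at least 2-fold higher with RA and 4 lower. The higher ones were Cd68 (a lysosomal protein of macrophages, 5.41 to 11.31), Krt79 (of the hair follicle and sebaceous duct, 5.23 to 13.20) and Fasn. The lower ones were the matrix genes Sparc (14.45 to 12.06) and Col3a1 (7.03 to 4.90), Tek (7.72 to 6.38) and Tubb3 (11.60 to 7.38). The list medians were -0.047 for fibroblast, -0.24 for melanocyte, -0.43 for endothelial, -0.054 for hair follicle and sebaceous gland, -0.22 for Merkel cell and neuron and 0.11 for muscle genes, each inside the central 95%, and the fibroblast and hair follicle medians turned to just above 0 after lowess over all probe sets (0.013 and 0.0017). With the floor at the 75th percentile the fibroblast (1.24th percentile, 4 genes) and Merkel cell lists (1.47th, 2 genes) came outside, as did the Merkel cell (1.54th) and hair follicle lists (98.5th) by their means and the endothelial list (2.39th) with values raised to the floor. The immune list was apart, with a median of 0.85, but only 3 of its 15 members were above the floor (Cd68, Cd74 and Cd3g), and without Cd68 it was inside the central 95%. In all, 14 of the 30 lists were apart, 9 higher and 5 lower. Some lists share members, such as Dsg3 and Dsc3 in both the spinous and the desmosome list, so these 14 are not separate results.

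**Figure D3:**
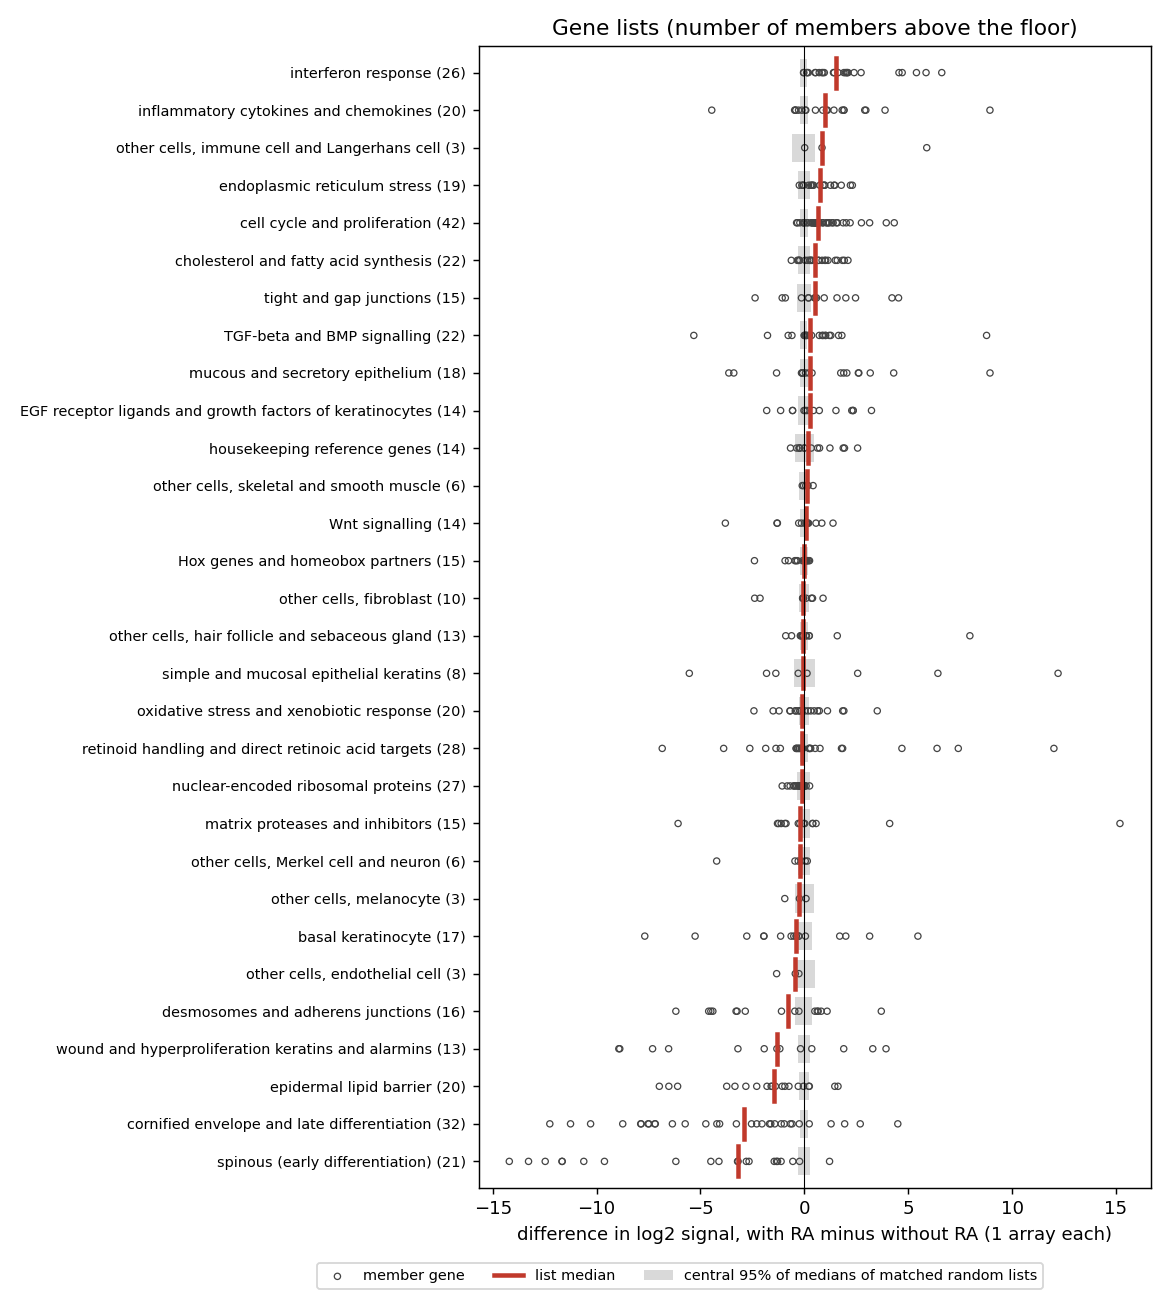
Difference in log2 signal, RA minus without RA, of each member above the floor (circles) for the 30 gene lists, with each list's median (red) and the central 95% of medians of 10000 matched random lists (grey), from 1 array per group. The spinous median of -3.21 and the cornified median of -2.90 lie furthest below, and the interferon median of 1.53 furthest above.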

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

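No paired analysis was possible because each group has 1 array, and no replicate could be left out. The 15 most changed genes in each direction and the other named genes kept their sign in every scaling, probe set and floor alternative wherever they differed by at least 2-fold: of 948 comparisons for 158 genes, 930 moved by less than the spread of genes of like signal, 18 moved by more and 0 reversed. The counts of 1125 higher and 804 lower genes stayed within 1.5 times of themselves under every scaling, floor and probe set rule (1091 to 1450 and 643 to 804), and the fold threshold moved them, to 1980 and 1757 at 1.5-fold and 435 and 285 at 4-fold. Of 329 comparisons for the 30 lists, 282 kept their sign and their side of the central 95% or moved little. No alternative tried changed the call or sign of the spinous, cornified, lipid barrier, wound, cell cycle, interferon, cytokine, tight junction, TGF-beta and endoplasmic reticulum stress lists, which were apart or, of those run for it, moved the muscle list, which was not, and which gave no value with the floor at the 75th percentile. By the median of absolute differences, added after the data were seen, 18 of the 30 lists lay above the central 95% of random lists. For the rest the cause was not tested, except that a different floor changes how many members count. With the mean in place of the median the sign turned for 7 lists, to 0.59 (retinoid), 1.54 (simple keratins) and 0.62 (hair follicle), which were then apart, and to -0.30 (Hox), 0.58 (protease), -0.24 (Wnt) and 0.13 (oxidative stress), which were not. The mean was -0.64 for basal, 0.64 for growth factor, 0.64 for cholesterol (then inside), 0.54 for reference, -0.30 for fibroblast and -0.82 for Merkel cell genes (then apart). Lowess over all probe sets gave -0.018 for retinoid, -0.30 for basal (then apart), 0.11 for oxidative stress, 0.31 for ribosomal and 0.89 for reference genes. Quantile normalization gave -0.017 for retinoid, 0.082 for oxidative stress, and put basal (-0.39), growth factor (0.34) and protease genes (-0.22) apart. Oxidative stress genes were at 0.090 after median centring, at 0.060 after lowess over probe sets with 1 gene (added after the data were seen) and at -0.21 without Txnrd1. The mean of a gene's probe sets put growth factors apart (0.44). Without a floor the mucous (0.020) and immune (0.020) lists came inside, and protease, melanocyte, endothelial and Merkel cell genes were at -0.038, 0.054, -0.038 and 0.026. With the floor at the 75th percentile growth factor (0.43), protease (-0.55), fibroblast (-0.89, 4 genes) and Merkel cell genes (-2.33, 2 genes) came apart, and simple keratins, Hox, Wnt, oxidative stress, melanocyte, endothelial and hair follicle genes were at 0.60, -0.45, 0.21, 0.31, -0.94, -1.33 and 0.24. Raising values to the floor put endothelial genes just apart (-0.43, 3 genes). Without the most changed member, desmosome genes (-0.46, without Dsg3) and immune genes (0.44, without Cd68) came inside. Signals near background and at the highest value limit what can be read: 93 probe sets were at the ceiling on both arrays.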

Other observations

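The tests of swapped labels, scaling, fibroblasts, differences between cultures, immune cells, bright probe sets, MHC class I and clade B serpins, and the Ly6 and transcription factor lists, were chosen after the results they bear on were seen, and those of glycolysis, lysosome, complement, respiratory chain and interferon genes and of neighbouring genes before.

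Genes of glycolysis and the hypoxia response, a list that was not among the 30 and was drawn up after Vegfa, Ero1a and Pgk1 had been seen and without them, were higher with RA. Of 28 members above the floor, 12 were at least 2-fold higher and 0 lower, and the median of 0.91 lay above all 10000 matched random lists. P4ha1, a collagen prolyl hydroxylase, went from 8.69 to 12.40, the glucose transporter gene Slc2a1 from 16.46 to 18.76, the glycolytic gene Tpi1 from 15.60 to 17.72 and Pfkl from 8.27 to 10.91. In a list of MHC class I and antigen processing genes drawn up after the data were seen, 6 of the 11 members above the floor that were in no fixed list were at least 2-fold higher and 0 lower, with a median of 1.03. Erap1 and Tapbp were higher by 2.80 and 2.15. Nuclear-encoded genes of the respiratory chain had a median of -0.016, lysosomal genes of 0.0098 and complement genes other than C3 of -0.049. Each lay inside the central 95%. Of the 26 lysosomal genes, 4 were at least 2-fold higher, among them Ctsl and Neu1, by 2.94 and 2.86. The 1 lower gene was Atp6ap1, by 1.12. After lowess over all probe sets the medians of the respiratory chain, lysosomal and complement genes were 0.29, 0.44 and 0.054, still inside the central 95%. That of glycolysis stayed above all random lists.

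The lists here were also drawn up after the data were seen, so that their medians describe what prompted them. Of 12 clade B serpins above the floor, 8 were at least 2-fold lower and 1 higher. Without the 4 that are named genes or in a fixed list, 4 of 8 were lower and 1 higher, with a median of -0.997. Ly6 and uPAR family genes split, with Psca and Ly6c higher by 7.84 and 7.02 and Ly6g6c and Ly6d lower by 7.11 and 4.68, and had a median of -0.61, and of -0.34 after lowess. Of 28 epithelial transcription factors above the floor, 10 were at least 2-fold lower, among them Cebpa (10.58 to 6.96), Klf5 (13.55 to 10.64) and Maf (7.87 to 5.59), and 1 was higher, Elf3 (6.77 to 14.22).

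Some changed genes lay next to each other in the order of the genes above the floor. For this, 14203 genes above the floor were ordered by assembly GRCr8, and all other genes between them were skipped. In that order, 12 runs of 4 or more genes in a row were all at least 2-fold changed one way. In 1000 shuffles of the order there were at most 5. These runs held 65 genes in all, a small part of the 1125 higher and 804 lower genes. Of the runs, 7 were lower and 5 higher. The longest, 12 and 8 genes, were the late envelope genes around Kprp, Flg and Rptn and the Sprr genes up to Ivl, and others held 6 clade B serpins, 5 kallikreins (Klk10 to Klk14) and 4 interleukin-36 genes. The 5 higher runs were Stra6, Islr, Islr2 and Pml, then Ifih1, Gca, Cobll1, Galnt3 and Ttc21b, then Nos2, Lgals5, Lgals9 and Ksr1, then Syngr2, Tk1, Afmid and Birc5, and last Cd300c2l1, Igsf7, Igsf7 l1 and Cd300c, receptor genes known from myeloid cells, higher by 1.03 to 2.49. A candidate explanation is regulation over whole gene clusters, which was not tested. Most of the lower runs are families of related genes, as is the higher run of Cd300 and Igsf7 genes, so shared probe signal was not excluded for these runs.

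The lower signal of epidermal differentiation genes with RA was weighed against technical explanations. Scaling that depends on brightness is argued against by the lowess correction, after which the median of the 53 spinous and cornified genes was -2.95, against -3.21 before. Only this size bears on such scaling, since random lists matched on mean signal shift along with the genes. Replacement of keratinocytes by fibroblasts is argued against by the 20 fibroblast markers, 0 of which were at least 2-fold higher, 10 of them being under the floor on both arrays. A swap of the 2 labels could not be decided by the median of the whole retinoid list, which mixes retinoid handling genes with direct targets. That median was -0.12, inside the central 95%, with 6 of 28 genes higher and 6 lower. The list's mean of 0.59, at the 99th percentile, and the sizes of Stra6 (12.02), Tgm2 (7.41), Dhrs3 (6.39) and Gprc5a (4.70) go with the labels as given. A swap was not tested otherwise. A difference between cultures that has nothing to do with RA, such as their density or stage, cannot be told apart from an effect of RA, since there was 1 array per group.

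Immune cells in the RA culture, as a source of the higher interferon response, have for them Cd68, higher by 5.89, Cd74, higher by 0.85, the immune list's place at the 99.5th percentile and the run of Cd300 and Igsf7 genes. Shared probe signal was not excluded for that run. Against immune cells, 1 of 15 markers was at least 2-fold higher, and 12 were under the floor on both arrays, among them the abundant leukocyte transcripts Tyrobp (3.06 and 3.15) and Lyz2 (3.76 and 3.75), singled out after their values were seen. C1qa, a complement gene also known from macrophages and not among these markers, was at 8.26 without RA and 8.20 with RA. It too was singled out after its values were seen. Brightness-dependent scaling is argued against by the size of the median after lowess, 1.53 for 27 genes, against 1.53 for 26 genes before. Higher interferon transcripts stay open: 0 of 8 measured interferon genes were at least 2-fold higher, but all lay under the floor, with a highest value of 3.66, where a change would not have been seen, so that the bound set beforehand could not exclude them. An effect of RA itself stays open as well, as does a difference between the cultures.

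Probe sets with no gene name showed a shift of their own. Of 1275 bright ones, with a mean signal in the 2.5 units below 16 (median 15.26 without RA and 14.31 with RA), 1208 were lower with RA, with a median of -0.92, or -0.86 over their 943 distinct pairs of values. Brightness-dependent scaling is argued against as the whole cause by the 294 probe sets with 1 gene in the same window (median 14.54 without RA and 14.48 with RA), whose median difference was -0.14, and -0.10 when weighted to the brightness of the unnamed ones in 10 bins, in 10 of which the unnamed median was lower. Repeated sequences read by many probe sets are a candidate explanation: 30.3% of the unnamed ones shared both values exactly with another probe set, against 1.02% of the named ones. These probe sets may pull the lowess curve over all probe sets, but no curve was fitted without them alone. No biological explanation was tested.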
